A study of Mus musculus with 28 samples.

How the data were processed

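Liver RNA of 28 male mice was hybridised to single-colour whole-transcript arrays with a biotin label, 1 array for each mouse, after an RNA integrity number above 8.0 had been required. Per the labels, the authors summarised the arrays with RMA, and the deposited values are log2 expression values, used here as deposited. The version of RMA is not given, nor is it stated whether all arrays were normalised in a single run. The groups were lifelong intermittent diet at 6 months (n = 6), 12 months (n = 7) and 24 months (n = 7), and a switch from moderate-fat food to the intermittent diet at 12 months with sampling at 24 months (n = 8). An array batch (G150, G151 or G152) was read from the array names: the 3 batches held 4, 1 and 1 livers at 6 months, 4, 2 and 1 at 12 months, 4, 1 and 2 at 24 months, and 6, 1 and 1 of the switched group.

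Of 35556 probe sets, 21218 name exactly 1 gene, 1881 name several and 12457 name none in the annotation used. The 1-gene probe sets name 18820 distinct genes, and for the 1386 genes with more than 1 probe set the one with the highest mean over all arrays stood for the gene. Members of fixed lists without such a probe set were not analysed here. No probe set was filtered out and no detection call was made.

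All 28 arrays entered 1 linear model in limma 3.58.1 (R 4.3.3), with the 4 groups and the array batch as fixed terms, followed by empirical Bayes moderation. Comparisons were 12 with 6 months, 24 with 6 months, 24 with 12 months, and switched with lifelong at 24 months. Tests were two-sided, and p was adjusted by Benjamini-Hochberg over all probe sets of a comparison, with 0.05 as the threshold. SE is the moderated standard error of a difference, and group means are given with the SD. Gene lists for functions and cell types, 48 with at least 5 measured genes, were tested with camera in limma at its preset correlation of 0.01 and again with the correlation estimated for each list. Their p was adjusted over all lists and the 4 comparisons, 192 tests in all. A list score of a liver is the mean over the list's genes of the difference from the mean of all arrays. Within-batch values are differences of group means in 1 batch, followed for a list by the median over its genes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the annotation and drew the figures.

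The rule for naming genes took, among genes that passed in a comparison, the 12 with the largest rise and the 12 with the largest fall, or the 10 with the smallest p where fewer than 6 passed. It added up to 4 members of each list with the smallest p and passed over predicted and unnamed genes, small RNAs and olfactory or vomeronasal receptors. The text prints 114 of the gene and comparison pairs that the rule takes, 80 of them passing. The groups, comparisons, tests, lists, this rule and the alternatives, apart from those named below as added, were chosen before the data were examined.

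The alternatives were no batch term, batch G150 alone, batches G151 and G152 alone, only the groups compared, the lowest 30 percent of probe sets left out, a repeated quantile normalisation, centring of arrays on their median, a mean-variance trend with robust moderation, array weights, the replicate number as a block together with batch, an estimated correlation in camera, and each array of a comparison left out in turn. Fits on 1-gene probe sets alone and without a pair of arrays that carry an added suffix in their name were added after the data were seen. The number of calls was compared with that of 100 splits of the livers of each comparison, the real one included. The pipeline was tested on simulated data with the arrays' own design and spread: of 67 probe sets moved by 1 log2 unit in each comparison it recovered 92.5% to 98.5%, of 67 moved by 0.5 it recovered 70.1% to 79.1%, and 3.70% to 5.43% of its calls were false. The moved probe sets were drawn from those that stood for a gene and lay above the lowest 30 percent in mean brightness. Recovery of dimmer probe sets was not simulated. In the same simulation camera called the list that was moved and 0 of the 48 others, but the simulated genes were independent of each other and correlated lists were not tested in this way.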

Results

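Gene expression was measured in the livers of 28 male C57BL/6J mice on single-colour whole-transcript arrays, 1 array for each mouse. All of the mice were on an intermittent diet, in which a week of moderate-fat food eaten freely (25% of its energy from fat) alternated with a week at 60% of the energy intake of control mice. Lifelong groups had followed the alternation since 9 weeks of age, and their livers were taken at 6 months (n = 6), 12 months (n = 7) and 24 months (n = 7). A switched group (n = 8) had eaten the moderate-fat food without interruption until 12 months of age, then followed the alternation, and was sampled at 24 months. Before sampling, the mice were fasted for 4 hours, given carboxymethyl cellulose by gavage and fasted for another 6 hours. Livers of mice on the control, calorie-restricted and continuous moderate-fat diets were not analysed here. The week of the diet cycle in which each mouse was sampled is not given in the sources used here. The values cover 35556 probe sets, and 21218 of these name exactly 1 gene. Array medians lay between 5.23 and 5.31 log2 units, and Pearson's r between pairs of arrays, taken across probe sets, which are not independent replicates, ranged from 0.978 to 0.992. The number of arrays in each group limits the precision of every difference given here. Differences are on the log2 scale, list values are medians over the measured genes of a list, and within-batch values follow the order of array batches G150, G151 and G152. Batches G151 and G152 held 1 or 2 livers of each group. The genes named are a selection from those that the rule for naming genes takes. The rule picks genes by their difference or p in the same comparison. Counts of livers on the stated side of a mean therefore follow in part from this choice for named genes and are not separate support. They also do not show the spread within the group that gives the mean.

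The comparison of 12 with 6 months asks how liver expression differed between young and middle-aged mice on the lifelong intermittent diet. Age and time on the diet increased together in the comparisons between ages. The week of the diet cycle, which is not known, may also have differed between the age groups. At 12 months, genes for making cholesterol and fatty acids lay higher and genes for oxidising fatty acids lay lower, as list shifts in camera in which 1, 1 and 3 of 20 genes passed. With an estimated correlation these shifts did not pass (adjusted p = 0.262, adjusted p = 0.285 and adjusted p = 0.318). Dmrta1, which encodes a DM-domain transcription factor, rose by 1.24 (SE 0.19), or 2.37-fold, from 5.57 ± 0.23 (SD, n = 6) to 6.82 ± 0.43 (SD, n = 7). Apoa4, an apolipoprotein of triglyceride-rich lipoproteins, rose by 0.77 (SE 0.12), and Hsd17b11, a dehydrogenase found on lipid droplets, fell by 0.77 (SE 0.11). With limma and Benjamini-Hochberg adjustment, 210 of 35556 probe sets passed, 129 higher and 81 lower, and they named 163 genes, 103 higher and 60 lower. Of the 210, 49 differed at least 1.5-fold. An unadjusted p under 0.05 was reached by 4643 probe sets, against 1778 given by chance. Each gene named for this comparison, passing or not, lay on the stated side of the 6-month mean in 7 of 7 livers at 12 months.

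Cholesterol synthesis had the largest list median, +0.61 over 20 measured genes. Tm7sf2, a sterol reductase, rose by 0.82 (limma adjusted p = 0.033) and the other 19 did not pass over all probe sets, whereas 17 rose when adjusted over the list alone. Squalene epoxidase Sqle (+1.68, adjusted p = 0.0636), Nsdhl (+1.00, adjusted p = 0.0655) and the sterol isomerase Ebp (+0.29, adjusted p = 0.0523) were among those that did not pass over all probe sets. The list shift had an adjusted p of 9.21e-14 in camera, adjusted p = 0.262 with an estimated correlation, and medians of 0.52, 0.81 and 0.74 within batches. Fatty acid synthesis genes had a median of +0.29 and within-batch medians of 0.35, 0.17 and 0.38. Camera gave an adjusted p of 9.63e-08, and adjusted p = 0.285 with an estimated correlation. The desaturase Fads1 rose by 0.39 (adjusted p = 0.0361), 19 genes of this list did not pass, and 11 rose when adjusted over the list alone. Scd1, which makes monounsaturated fatty acids, differed by +0.19 (adjusted p = 0.0636) and Acly, which supplies cytosolic acetyl-CoA, by +0.80 (adjusted p = 0.0937). Among 13 genes of glycolysis and glucose uptake, the regulatory protein Gckr (+0.36), the hepatic glucose transporter Slc2a2 (+0.39) and ketohexokinase Khk (+0.44) rose, with adjusted p of 0.0275, 0.033 and 0.0463, and 10 did not pass. Adjusted over the list alone, 5 rose; the list median was +0.13, with 0.11, 0.12 and 0.10 within batches. The list had a camera adjusted p of 0.000716, and adjusted p = 0.0774 with an estimated correlation.

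Targets of PPARA, the fatty acid sensing receptor, and genes of fatty acid oxidation had a median of -0.28. The 6-month livers differed among themselves, with list scores of 0.68, 0.70 and 0.72 in replicates 2, 3 and 4. Scores of 6-month replicates 1, 5 and 6 were -0.29, 0.04 and -0.25, within the 12-month range of -0.49 to 0.35, so that the fall was not uniform. Lipid droplet scores divided the same 6-month livers, with -0.11, -0.14 and -0.02 in replicates 2, 3 and 4. They were -0.70, -0.45 and -0.62 in replicates 1, 5 and 6. Whether these livers came from different weeks of the diet cycle is not known. Ehhadh, the peroxisomal bifunctional enzyme, fell by 1.16 (adjusted p = 0.0458), the fatty acid hydroxylase Cyp4a31 fell by 0.92 (adjusted p = 0.0463) and Hadhb, a subunit of the mitochondrial trifunctional protein, fell by 0.46 (adjusted p = 0.033). The remaining 17 of 20 genes did not pass, the thioesterase Acot2 among them (-1.49, adjusted p = 0.0898), and 10 fell when adjusted over the list alone. Within batches the list medians were -0.21, -0.68 and -0.07, and the camera adjusted p was 1.02e-09, adjusted p = 0.318 with an estimated correlation. Xenobiotic metabolism genes had a median of +0.17 (within batches 0.17, 0.22 and 0.23; camera adjusted p = 0.00113, adjusted p = 0.293 with an estimated correlation). The sulfotransferase Sult1a1 (+0.61, adjusted p = 0.0304) and the glutathione transferase Gstt1 (+0.29, adjusted p = 0.0498) rose, 16 genes did not pass, and adjusted over the list alone 6 rose and 1 fell. Heat shock genes had a median of -0.18 and -0.12, -0.40 and -0.22 within batches, with 0 of 12 genes passing limma over all probe sets and 4 lower when adjusted over the list alone. In camera the adjusted p was 0.00049, and adjusted p = 0.34 with an estimated correlation. Markers of Kupffer cells and macrophages had a median of -0.19, with 0 of 18 genes passing limma over all probe sets or adjusted over the list alone, and medians of -0.24, 0.03 and -0.38 within batches. For the list, camera gave adjusted p = 0.0446, and adjusted p = 0.751 with an estimated correlation. Genes of MHC class II antigen presentation lay in the same direction (-0.38; camera adjusted p = 0.0104, adjusted p = 0.578 with an estimated correlation). Here 0 of 8 passed limma over all probe sets or adjusted over the list alone, and medians across batches were -0.61, 0.25 and -0.68, positive in G151. The macrophage call was lost without 6-month replicate 1, 3, 5 or 6 and without 12-month replicate 1, 2, 3 or 7, with adjusted p up to 0.16, and the MHC class II call without 6-month replicate 1 (adjusted p = 0.0741). Not all immune lists fell: interferon response, MHC class I and acute phase genes were called higher in camera. In these lists 5, 6 and 4 of 7 livers at 12 months lay above the 6-month mean score. Male-biased genes were called lower, in 7 of 7 livers. Each of these further calls was lost in at least 1 fit that left out 1 liver. With an estimated correlation 0 of the 17 lists called in this comparison passed. Hepatocyte markers had a median of 0.00 and a mean of -0.02, and 0 of 14 passed limma over all probe sets (camera adjusted p = 0.509).

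Outside these lists, the steroid hydroxylase Cyp17a1, a female-biased gene in mouse liver, rose by 1.25 (adjusted p = 0.0275) and the glutathione transferase Gstt3 by 0.97 (adjusted p = 0.00535). The vitamin C transporter Slc23a1 rose by 0.84 (adjusted p = 0.0275) and Stap1, a signalling adaptor, by 1.21 (adjusted p = 0.0361). The carboxylesterase Ces4a was 2.3-fold lower (adjusted p = 0.0194), the collagen gene Col12a1 fell by 0.85 (adjusted p = 0.0327) and Slc35f1 fell by 1.03 (adjusted p = 0.0311). The count of 210 depended on single livers: it was 546, 9, 11, 7, 403 and 8 without 6-month replicates 1 to 6 in turn, and 345, 87, 12, 8, 32 and 35 without 12-month replicates 1 to 6 in turn. Hsd17b11, Dmrta1, Gstt3 and Apoa4 passed in each of the 13 fits that left out 1 liver, and the other 16 named genes that passed were lost in at least 1; batch G150 alone gave 0 probe sets in limma, with 2497 at an unadjusted p under 0.05. G151 with G152 also gave 0, with 2957 at an unadjusted p under 0.05. The count was 22 in a fit of the 2 groups alone, 108 with no batch term, 122 with a replicate block (85 of them among the 210) and 46 without the pair of arrays with an added suffix. It was 518 with array weights and 332 over probe sets with 1 gene.

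The comparison of 24 with 6 months asks the same of old and young mice on the lifelong intermittent diet. Immunoglobulin and B cell transcripts, cholesterol synthesis, MHC class I and acute phase genes lay higher in old livers, and male-biased genes, heat shock genes and chaperones of the endoplasmic reticulum lay lower, as list shifts in camera in which 3 of 11 plasma cell, 5 of 12 B cell, 10 of 20 cholesterol synthesis, 6 of 11 MHC class I, 5 of 23 acute phase, 7 of 18 male-biased, 4 of 12 heat shock and 4 of 22 unfolded protein response genes passed. With an estimated correlation camera passed 0 of the 21 lists, with 9 at an unadjusted p under 0.05, and these 8 had adjusted p from 0.216 to 0.365. Igkc, the immunoglobulin kappa constant region, rose by 3.52 (SE 0.61), or 11.5-fold, from 4.47 ± 0.17 (SD, n = 6) to 7.94 ± 1.06 (SD, n = 7). Cyp17a1 rose by 2.11 (SE 0.24), or 4.33-fold, and Ugt2b38, a male-biased glucuronosyltransferase, fell by 1.05 (SE 0.12). In limma with Benjamini-Hochberg adjustment 1681 of 35556 probe sets passed, 747 higher and 934 lower, naming 1217 genes, 576 higher and 641 lower. Which direction held more probe sets depended on the setting: repeated quantile normalization gave 852 higher and 812 lower, and a fit of the 2 groups alone 368 higher and 368 lower. Of the 1681, 398 differed at least 1.5-fold, and 6832 probe sets had an unadjusted p under 0.05. The genes named for this comparison lay on the stated side of the 6-month mean in 7 of 7 old livers, except Igha, Itgax, Hyou1 and Lepr, for which 6 of 7 did.

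Among 12 B cell markers, 5 rose and 7 did not pass, and 9 rose when adjusted over the list alone. The immunoglobulin mu chain Ighm rose by 1.35 (limma adjusted p = 0.00408), Cd79b of the B cell receptor by 0.84 (adjusted p = 0.0375), Ms4a1, which encodes CD20, by 0.75 (adjusted p = 0.0295) and the B cell lectin Cd22 by 0.59 (adjusted p = 0.0243). The list median was +0.47 and 0.52, 0.48 and 0.36 within batches, and 6 of 7 old livers lay above the 6-month mean score. The list's camera adjusted p was 3.11e-06, adjusted p = 0.262 with an estimated correlation. B cell scores of old replicates 2 and 4, -0.20 and -0.33, lay within the 6-month range of -0.48 to -0.05. The same livers were the lowest old livers in macrophage scores (-0.44 and -0.52) and chemokine and NF-kB scores (-0.36 and -0.32). They were also the lowest in T and NK cell scores (-0.25 and -0.21), so that the rises of these immune lists are not independent of each other. Plasma cell markers had a median of +0.35 (0.34, 0.60 and 0.36 within batches), with 3 of 11 risen over all probe sets and 7 adjusted over the list alone. Camera gave an adjusted p of 5.76e-05, and adjusted p = 0.216 with an estimated correlation. The 3 plasma cell genes that rose were Igkc (adjusted p = 0.00197), the joining chain Jchain (+1.61, adjusted p = 0.00341) and the alpha heavy chain Igha (+1.53, adjusted p = 0.0158); probes of immunoglobulin genes can hybridise with related segments. Macrophage markers had a median of +0.43 and 0.52, 0.33 and 0.20 within batches, in 5 of 7 old livers. The list had a camera adjusted p of 4.3e-05, and adjusted p = 0.535 with an estimated correlation. Lysozyme Lyz2 (+1.00, adjusted p = 0.0334), Gpnmb (+1.23, adjusted p = 0.0347) and the integrin Itgax (+0.71, adjusted p = 0.0491) rose, 15 of 18 did not pass, and 5 rose when adjusted over the list alone. Neutrophil markers had a median of +0.28 and 0.32, 0.24 and 0.18 within batches, in 6 of 7 old livers, with 0 of 12 passing limma over all probe sets or adjusted over the list alone (camera adjusted p = 0.00243, adjusted p = 0.451 with an estimated correlation). T and NK cell markers had a median of +0.16 and 0.08, 0.39 and 0.16 within batches, in 5 of 7 old livers, with 0 of 20 passing limma over all probe sets or adjusted over the list alone (camera adjusted p = 0.0399, adjusted p = 0.636 with an estimated correlation). The T and NK cell call was lost without 6-month replicate 2, 4 or 5 and without 24-month replicate 1, 3 or 7, with adjusted p up to 0.163. It was also lost with no batch term, in batch G150 alone, with the lowest 30 percent of probe sets left out, with quantile normalization repeated, with a replicate block and without the pair of arrays with an added suffix. MHC class II genes lay lower at 12 than at 6 months as a list shift in camera, with 0 of 8 passing limma and adjusted p = 0.578 with an estimated correlation. At 24 against 6 months they had a median of +0.11, with 1 of 8 risen, and did not pass as a list (camera adjusted p = 0.255). Xenobiotic metabolism genes did not either (+0.11, camera adjusted p = 0.364), with 3 of 18 risen and 1 fallen. Endothelial markers (-0.08, camera adjusted p = 0.242) and hepatocyte markers (-0.02, camera adjusted p = 0.3) did not pass as lists.

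**Figure D1:**
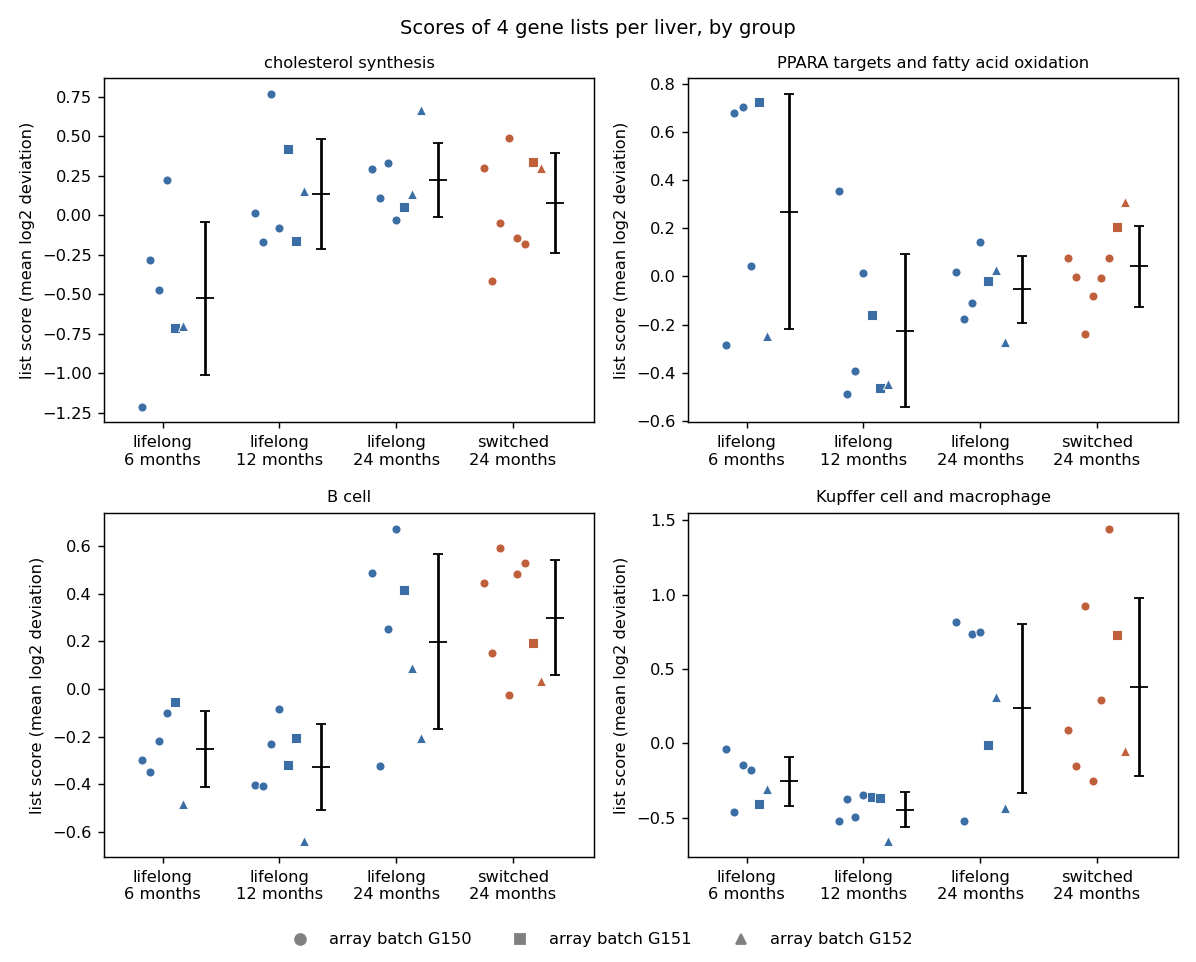
Scores of gene lists (mean over genes of each gene's log2 difference from its mean over all arrays) in single livers of lifelong mice at 6, 12 and 24 months and of switched mice at 24 months, n = 6, 7, 7 and 8. Each point is 1 liver, its marker shape gives the array batch, and bars show the mean ± SD; scores are not adjusted for batch, and the B cell score lay above the 6-month mean in 6 of 7 livers at 24 months.

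Antigen presentation by MHC class I had a median of +0.32 (0.29, 0.50 and 0.36 within batches), with 6 of 11 genes risen, 5 not passing and 9 risen when adjusted over the list alone. In camera the adjusted p was 3.07e-06, and adjusted p = 0.262 with an estimated correlation. The immunoproteasome subunit Psmb9 rose by 0.67 (adjusted p = 0.0178), the peptide transporter Tap1 by 0.60 (adjusted p = 0.0199) and H2-T23 by 0.34 (adjusted p = 0.018). Interferon response genes, which share 4 genes with other lists, had a median of +0.30 and 0.20, 0.44 and 0.37 within batches (camera adjusted p = 4.19e-06, adjusted p = 0.34 with an estimated correlation), with 5 of 22 risen and 7 when adjusted over the list alone. Among chemokines and NF-kB targets, Nfkb2 (+0.45, adjusted p = 0.0011) and the adhesion molecule Icam1 (+0.63, adjusted p = 0.0234) were 2 of 4 that rose, 20 did not pass, and 9 rose when adjusted over the list alone. That list had a median of +0.45, in 5 of 7 old livers, and 0.53, 0.22 and 0.43 within batches. For the list, camera gave adjusted p = 8.09e-06, and adjusted p = 0.365 with an estimated correlation. Acute phase genes had a median of +0.25 and 0.19, 0.41 and 0.31 within batches (camera adjusted p = 3.07e-06, adjusted p = 0.365 with an estimated correlation), with 5 of 23 risen; adjusted over the list alone 10 rose and 1 fell. Serum amyloid Saa2 rose by 2.58 (adjusted p = 0.0387), lipocalin Lcn2 by 2.08 (adjusted p = 0.0335) and Itih4 by 0.35 (adjusted p = 0.00474). Lysosome and autophagy genes had a median of +0.16 (0.16, 0.03 and 0.26 within batches), and the protease Ctsd (+0.36, adjusted p = 0.00251) and the cholesterol carrier Npc2 (+0.38, adjusted p = 0.00368) were among 4 of 18 that rose, against 8 when adjusted over the list alone. The list's camera adjusted p was 0.000157, adjusted p = 0.096 with an estimated correlation.

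In cholesterol synthesis, 10 of 20 genes rose, 10 did not pass and 18 rose when adjusted over the list alone. Sqle rose by 1.94 (adjusted p = 0.00933), the sterol reductases Dhcr7 and Tm7sf2 by 0.83 (adjusted p = 0.0101) and 0.77 (adjusted p = 0.0104), and Ebp by 0.35 (adjusted p = 0.0049). The median was +0.68 and 0.53, 0.78 and 0.94 within batches, with 7 of 7 old livers above the 6-month mean score. Camera gave an adjusted p of 7.39e-13, and adjusted p = 0.285 with an estimated correlation. Fatty acid synthesis genes had a median of +0.31 and 0.30, 0.25 and 0.41 within batches. The list had a camera adjusted p of 4.57e-07, and adjusted p = 0.314 with an estimated correlation. Fads1 (+0.43, adjusted p = 0.00416), the lipase Pnpla3 (+1.01, adjusted p = 0.0151), the acetyl-CoA synthetase Acss2 (+1.00, adjusted p = 0.0172) and Scd1 (+0.20, adjusted p = 0.0184) were among 5 of 20 that rose, and 8 rose when adjusted over the list alone. The fatty acid transporter Cd36 (+1.11, adjusted p = 0.016) and Apoa4 (+0.80, adjusted p = 0.000616) rose in the lipid droplet list, in which 3 of 16 rose over all probe sets and 5 adjusted over the list alone. That list's median was +0.41 but had the opposite sign in G151 (0.27, -0.38 and 0.83; camera adjusted p = 0.0104, adjusted p = 0.537 with an estimated correlation). Its call was lost without 6-month replicate 1 (adjusted p = 0.0626) and without 6-month replicate 6 (adjusted p = 0.0941). The PPARA list had a median of -0.16, with 1 of 20 fallen, 3 when adjusted over the list alone, and medians of -0.19, -0.55 and 0.09 within batches. In camera the adjusted p was 0.0019, and adjusted p = 0.621 with an estimated correlation.

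Male-biased liver genes had a median of -0.71 and -0.62, -0.28 and -0.97 within batches, and 7 of 7 old livers lay below the 6-month mean score. For the list, camera gave adjusted p = 8.54e-09, and adjusted p = 0.262 with an estimated correlation. Of 18 such genes 7 fell and 11 did not pass, and 13 fell when adjusted over the list alone. Besides Ugt2b38 (adjusted p = 6.56e-05), the cytochromes Cyp4a12b and Cyp2d9 fell by 1.28 (adjusted p = 0.018) and 0.43 (adjusted p = 0.0122), and Selenbp2 fell by 1.11 (adjusted p = 0.021). Female-biased genes had a median of +0.12 and 0.02, 0.18 and 0.35 within batches, with 3 of 15 risen and 6 when adjusted over the list alone. The list's camera adjusted p was 0.00561, adjusted p = 0.34 with an estimated correlation. The 3 female-biased genes that rose were Cyp17a1 (adjusted p = 4.32e-05), Cyp2b9 (+3.22, adjusted p = 0.0129) and the transporter Slc22a26 (+2.00, adjusted p = 0.00317). Heat shock genes had a median of -0.26 (-0.26, -0.28 and -0.43 within batches), with 4 of 12 fallen and 7 when adjusted over the list alone. Camera gave an adjusted p of 3.1e-05, and adjusted p = 0.285 with an estimated correlation. Hsph1 fell by 0.92 (adjusted p = 0.00686) and the co-chaperone Dnajb1 fell by 0.50 (adjusted p = 0.0206). In the unfolded protein response list 4 of 22 genes fell, 18 did not pass and 9 fell when adjusted over the list alone. They were the chaperone Hspa5 (-0.61, adjusted p = 0.00319), Dnajb9 (-0.70, adjusted p = 0.00409), Creld2 (-1.06, adjusted p = 0.00631) and Hyou1 (-0.73, adjusted p = 0.018). The list median was -0.15, of opposite sign in G151 (-0.16, 0.06 and -0.53; camera adjusted p = 4.3e-05, adjusted p = 0.34 with an estimated correlation).

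Further large rises were those of the transporter Slc22a27 (+2.18, adjusted p = 0.00078), the metallothionein Mt2 (+2.09, adjusted p = 0.00374) and the nicotinic receptor subunit Chrna4 (+2.29, adjusted p = 0.00815). Ces4a fell by 1.50 (adjusted p = 0.000385), the leptin receptor Lepr fell by 1.49 (adjusted p = 0.0316), the retinol dehydrogenase Hsd17b6 fell by 1.22 (adjusted p = 0.000637) and Pfkfb3, a regulator of glycolysis, fell by 1.05 (adjusted p = 0.0135). In the glycolysis list, to which Pfkfb3 belongs, 3 of 13 genes rose, 1 fell and 9 did not pass, and adjusted over the list alone 5 rose and 1 fell. Its median was +0.20, with 0.18, 0.09 and 0.17 within batches. The list had a camera adjusted p of 0.000667, and adjusted p = 0.0774 with an estimated correlation. The count of 1681 became 1058, 831, 1106 and 846 without 6-month replicates 2, 3, 4 and 6 in turn, 1056 without 24-month replicate 3, 194 in batch G150 alone, 3 in G151 with G152, and 736 in a fit of the 2 groups alone. Of the 50 named genes that passed, 28 did so in each of the 13 fits that left out 1 liver, among them Igkc, Jchain, Igha, Ighm, Cyp17a1, Ugt2b38, Sqle and Hspa5; Cd22, Ms4a1, Cd79b, Saa2, Lcn2 and Lyz2 were among those that did not.

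The comparison of 24 with 12 months asks which differences lay between middle and old age. Macrophage, B cell and MHC class II genes lay higher at 24 months as list shifts in camera, in which 0 of 18, 1 of 12 and 0 of 8 genes passed limma over all probe sets. With an estimated correlation these shifts did not pass (adjusted p = 0.262, adjusted p = 0.0774 and adjusted p = 0.334). Sorl1, a sorting receptor, rose by 0.72 (SE 0.10), or 1.65-fold, from 5.51 ± 0.17 (SD, n = 7) to 6.20 ± 0.23 (SD, n = 7). Bmp10, a ligand of the BMP family, fell by 0.56 (SE 0.09) and the natriuretic peptide receptor Npr3 fell by 0.48 (SE 0.07). Cd79b rose by 1.25 (SE 0.23), or 2.38-fold, and Setbp1 by 0.63 (SE 0.11). In limma, 9 of 35556 probe sets passed, 5 higher and 4 lower, with 3953 at an unadjusted p under 0.05. The adjusted p was 0.00793 for Sorl1, 0.014 for Bmp10, 0.014 for Npr3, 0.0439 for Cd79b and 0.0439 for Setbp1. Another of the 9 named Ap3m1 (-0.37, adjusted p = 0.0439); this probe set is not the brightest of its gene, falls outside the rule for naming genes and was chosen after its value was seen. The remaining 3 name no single gene. Among the genes with the smallest p that did not pass were Zfp9 (-0.84), Ugt2b38 (-0.62) and the lysosomal phospholipase Pla2g15 (+0.47), each with an adjusted p of 0.0615. Apart from Ap3m1, which was not counted, each gene named for this comparison lay on the stated side of the 12-month mean in 7 of 7 livers at 24 months, except H2-Ob and Cyp17a1, with 6 of 7.

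Macrophage markers had a median of +0.68 and 0.81, 0.32 and 0.67 within batches, and 6 of 7 livers at 24 months lay above the 12-month mean score. In camera the adjusted p was 4.72e-15, and adjusted p = 0.262 with an estimated correlation. Adjusted over the list alone 14 of 18 rose, whereas 0 passed limma over all probe sets; Lyz2 differed by +1.19 (adjusted p = 0.0798). B cell markers had a median of +0.57 and 0.59, 0.55 and 0.64 within batches, in 7 of 7 livers. For the list, camera gave adjusted p = 2.2e-13, and adjusted p = 0.0774 with an estimated correlation. Besides Cd79b, the other 11 of 12 did not pass over all probe sets, Ms4a1 (+0.91, adjusted p = 0.0749) and Cd22 (+0.71, adjusted p = 0.0653) among them, and 10 rose when adjusted over the list alone. Plasma cell markers had a median of +0.33 and 0.27, 0.70 and 0.08 within batches, with 0 of 11 passing limma over all probe sets and 5 risen when adjusted over the list alone. The list's camera adjusted p was 5.76e-05, adjusted p = 0.216 with an estimated correlation. MHC class II genes had a median of +0.56 (0.71, 0.22 and 0.72 within batches), in 5 of 7 livers, with scores from -0.72 to 0.97 at 24 months. H2-Ob differed by +0.81 (adjusted p = 0.0615), and adjusted over the list alone 2 of 8 rose. Camera gave an adjusted p of 5.44e-06, and adjusted p = 0.334 with an estimated correlation. In MHC class I (+0.19; 0.20, 0.09 and 0.17 within batches), H2-T23 differed by +0.39 (adjusted p = 0.0615) and 2 of 11 rose when adjusted over the list alone. The list had a camera adjusted p of 0.00056, and adjusted p = 0.365 with an estimated correlation. Chemokines and NF-kB targets had a median of +0.39 and 0.52, 0.10 and 0.14 within batches, in 5 of 7 livers, with 6 of 24 risen when adjusted over the list alone. In camera the adjusted p was 2.2e-09, and adjusted p = 0.262 with an estimated correlation. Male-biased genes had a median of -0.41 and -0.28, -0.18 and -0.57 within batches, with 3 of 18 fallen when adjusted over the list alone. For the list, camera gave adjusted p = 4.57e-07, and adjusted p = 0.262 with an estimated correlation. Female-biased genes had a median of +0.12 and 0.12, 0.36 and 0.26 within batches, and adjusted over the list alone 4 of 15 rose. The list's camera adjusted p was 0.0045, adjusted p = 0.34 with an estimated correlation. Among female-biased genes, Cyp2b9 differed by +3.55 (adjusted p = 0.0615) and Cyp17a1 by +0.86 (adjusted p = 0.157). The PPARA list lay lower at 12 than at 6 months in camera, with 3 of 20 passing limma and adjusted p = 0.318 with an estimated correlation. At 24 against 12 months it had a median of +0.10 and 0.03, 0.02 and 0.18 within batches, in 6 of 7 livers. In that comparison 0 of 20 passed limma over all probe sets or adjusted over the list alone. The shift had a camera adjusted p of 0.00651, and adjusted p = 0.629 with an estimated correlation, and the call was lost without 12-month replicate 6 (adjusted p = 0.0648) and in batch G150 alone. Xenobiotic metabolism genes lay higher at 12 than at 6 months in camera, with 2 of 18 passing limma and adjusted p = 0.293 with an estimated correlation. At 24 against 12 months these genes had a median of -0.10 and -0.14, -0.19 and -0.01 within batches, in 5 of 7 livers, with 0 of 18 passing limma over all probe sets or adjusted over the list alone. Their camera adjusted p was 0.0179, and adjusted p = 0.435 with an estimated correlation, and the call was lost without 24-month replicate 5 or 7 and without the pair of arrays with an added suffix, with adjusted p up to 0.106. The count of 9 became 5, 5, 5, 4 and 5 without 12-month replicates 2, 3, 5, 6 and 7 in turn, and 3, 4, 124, 1, 3 and 68 without 24-month replicates 2 to 7 in turn. Sorl1 passed in each of the 14 fits that left out 1 liver; Bmp10 and Npr3 were each lost without 24-month replicate 5, Setbp1 in 10 and Cd79b in 11 of these fits. The 5 calls were all lost in batch G150 alone and with a replicate block, where limma gave 0 and 0 probe sets (3415 and 3771 at an unadjusted p under 0.05). They were also lost in G151 with G152, with 0 probe sets (2037 at an unadjusted p under 0.05), and in a fit of the 2 groups alone, with 1. With no batch term 3 probe sets passed, those of Sorl1, Bmp10 and Npr3, and Setbp1 and Cd79b were lost there, with repeated quantile normalization and without the pair of arrays with an added suffix.

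The comparison of switched with lifelong livers at 24 months asks whether starting the intermittent diet at 12 months, after continuous moderate-fat food, leaves a different liver from following it for life. In switched livers female-biased genes lay higher and male-biased genes lower. Cyp2b13 (probe set 10551209), a female-biased cytochrome, rose by 3.26 (SE 0.37), or 9.61-fold, from 3.83 ± 1.10 (SD, n = 7) to 7.07 ± 0.80 (SD, n = 8). Hao2 (probe set 10500570), a female-biased peroxisomal oxidase, rose by 1.80 (SE 0.27), from 4.12 ± 0.92 (SD, n = 7) to 5.83 ± 0.60 (SD, n = 8), and the carbonyl reductase Cbr1 (probe set 10436967) by 0.41 (SE 0.07). Susd4 (probe set 10352439), a male-biased complement regulator, fell by 1.24 (SE 0.21), from 9.19 ± 0.43 (SD, n = 7) to 7.94 ± 0.62 (SD, n = 8), and the male-biased cytochrome Cyp2d9 (probe set 10425763) fell by 0.54 (SE 0.09). These are the 5 genes named by the 7 of 35556 probe sets that passed limma, 5 higher and 2 lower, with 2696 at an unadjusted p under 0.05. The adjusted p was 0.000118 for Cyp2b13, 0.0094 for Hao2, and 0.0341 for each of Cbr1, Susd4 and Cyp2d9. Each lay on the stated side of the lifelong mean in 8 of 8 switched livers, except Cyp2d9, with 7 of 8. Cyp2b13, Hao2 and Sult3a1 are dim, at percentiles 34.2, 33.6 and 7.41 of mean brightness over all probe sets, so that their folds may be compressed. Probes of Cyp2b, Mup and other gene families can hybridise with related members.

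**Figure D2:**
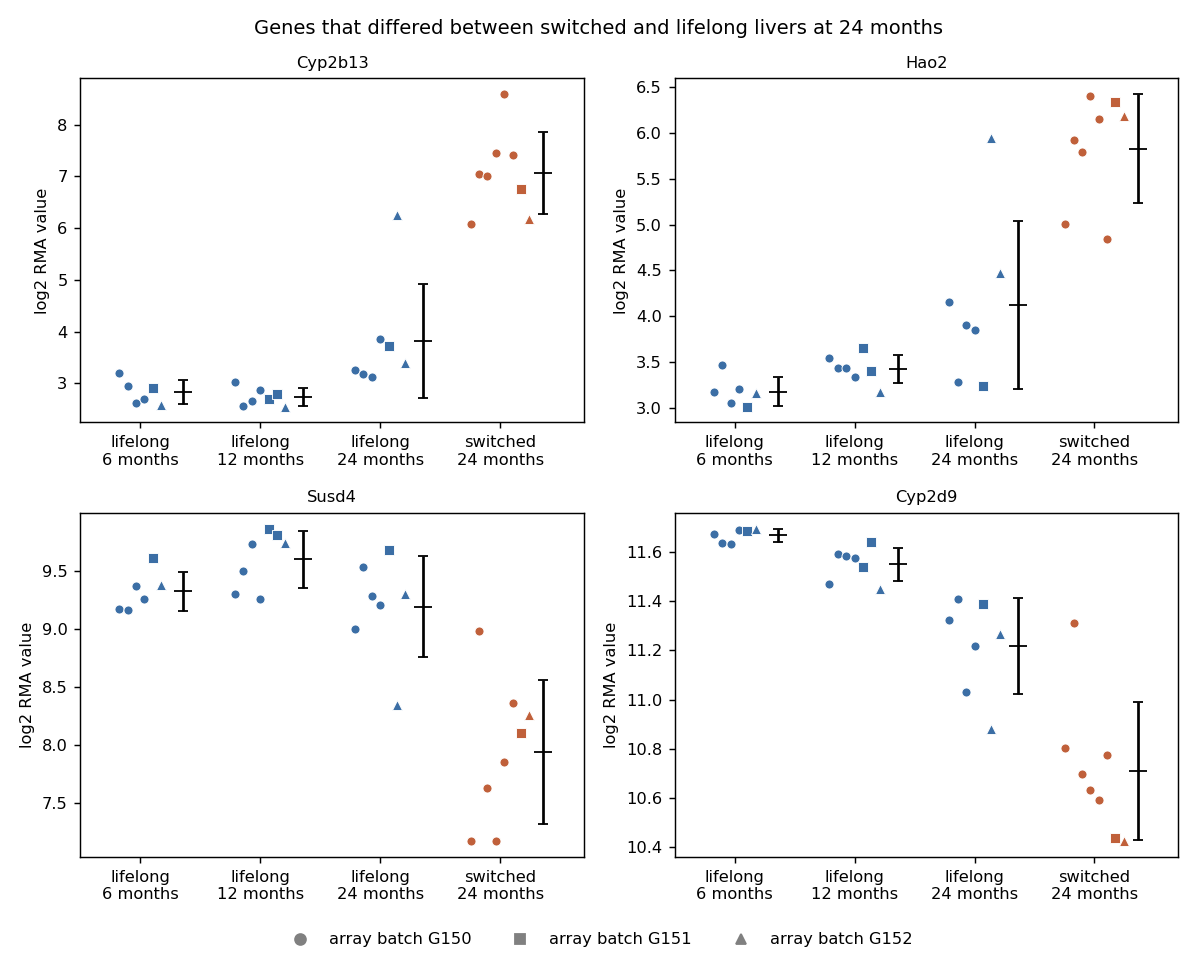
Log2 expression in single livers of 4 genes that passed between switched (n = 8) and lifelong (n = 7) mice at 24 months, with the younger lifelong groups beside them. Each point is 1 liver, its marker shape gives the array batch, and bars show the mean ± SD; Cyp2b13 averaged 7.07 ± 0.80 (SD, n = 8) in switched and 3.83 ± 1.10 (SD, n = 7) in lifelong livers.

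Female-biased liver genes had a median of +0.60 over 15 genes and 0.73, 0.88 and 0.36 within batches, and 8 of 8 switched livers lay above the lifelong mean score. The camera adjusted p was 2.19e-17, adjusted p = 0.00355 with an estimated correlation. Besides Cyp2b13 and Hao2, 13 did not pass over all probe sets, and 10 rose when adjusted over the list alone. The sulfotransferases Sult3a1 (+1.74, adjusted p = 0.0632) and Sult1e1 (+0.67, adjusted p = 0.17) were among the 13. Male-biased liver genes had a median of -0.65 over 18 genes and -0.58, -0.93 and -0.45 within batches, and 8 of 8 switched livers lay below the lifelong mean score. The camera adjusted p was 9.64e-21, adjusted p = 0.0398 with an estimated correlation. Susd4 and Cyp2d9 fell, 16 did not pass over all probe sets and 14 fell when adjusted over the list alone. Mup21, a major urinary protein gene (-0.93, adjusted p = 0.104), and the transporter Slco1a1 (-1.52, adjusted p = 0.188, in 7 of 8 livers) were among the 16. A test added after the scores were seen compared the mean scores of the 2 groups over all 6435 splits of the 15 livers. The female-biased score was higher by 0.88 in switched livers (two-sided exact permutation p = 0.000311) and the male-biased score differed by -0.76 (two-sided exact permutation p = 0.00295). In lifelong livers both mean scores differed in the same direction with age, though list shifts between ages did not pass with an estimated correlation. At 6, 12 and 24 months and in switched livers, male-biased scores averaged 0.60, 0.44, -0.04 and -0.80. Female-biased scores averaged -0.65, -0.51, 0.03 and 0.90 in the same order. Between 6 and 24 months the rise of the female-biased score came largely from Cyp17a1, Cyp2b9 and Slc22a26. The median of the female-biased list differed less between these ages than between switched and lifelong livers. Cholesterol synthesis scores did not follow the stepwise course of the sex-biased scores, with -0.53, 0.14, 0.22 and 0.08. That course was not particular to sex-biased genes, since some other lists followed it. Acute phase scores averaged -0.39, -0.16, 0.09 and 0.35, and interferon response scores -0.24, -0.07, 0.09 and 0.17. Scores of fetal and liver tumour genes averaged -0.17, -0.08, 0.03 and 0.17.

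**Figure D3:**
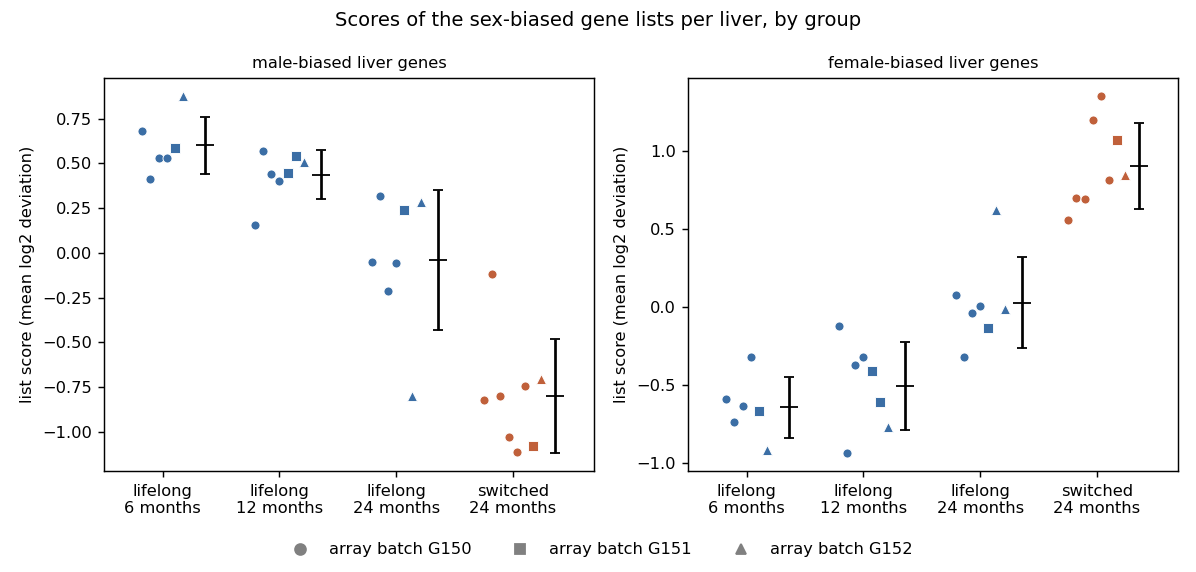
Scores of male-biased and female-biased liver genes (mean over genes of each gene's log2 difference from its mean over all arrays) in single livers of the 4 groups, n = 6, 7, 7 and 8. Each point is 1 liver, its marker shape gives the array batch, and bars show the mean ± SD, not adjusted for batch; the female-biased score averaged 0.90 in switched and 0.03 in lifelong livers at 24 months.

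Lipid droplet and steatosis genes had a median of +0.39 in switched against lifelong livers and 0.26, 0.98 and 0.52 within batches, with 8 of 8 switched livers above the lifelong mean score. Camera gave an adjusted p of 7.02e-08, and adjusted p = 0.262 with an estimated correlation. Here 0 of 16 passed limma over all probe sets and 6 rose when adjusted over the list alone. Adipose tissue markers, which share Fabp4 and Cidec with this list, did not pass as a list. Their mean score was -0.06 in lifelong and 0.16 in switched livers. The lipoprotein receptor Vldlr differed by +0.74 (adjusted p = 0.122), the lipid droplet protein Cidea by +2.50 (adjusted p = 0.235), Cd36 by +0.94 (adjusted p = 0.289) and the acyltransferase Mogat1 by +0.95 (adjusted p = 0.343). Complement and coagulation genes had a median of -0.07 and -0.08, -0.17 and -0.10 within batches, with 0 of 24 passing limma over all probe sets and 6 fallen when adjusted over the list alone. The list had a camera adjusted p of 3.07e-06, and adjusted p = 0.262 with an estimated correlation. C9 (-0.50, adjusted p = 0.118), C6 (-0.77, adjusted p = 0.225) and C8a (-0.34, adjusted p = 0.201), which form the membrane attack complex, did not pass over all probe sets; C6 and C8a are also on the male-biased list. Extracellular matrix genes had a median of +0.20 and 0.13, 0.62 and 0.04 within batches, and 0 of 26 passed limma over all probe sets or adjusted over the list alone. In camera the adjusted p was 6.16e-08, and adjusted p = 0.285 with an estimated correlation. The collagen gene Col1a1 differed by +0.33 (adjusted p = 0.469) and the collagenase Mmp13 by +0.52 (adjusted p = 0.381). Xenobiotic metabolism genes had a median of +0.15 and 0.17, 0.28 and 0.02 within batches. For the list, camera gave adjusted p = 0.00049, and adjusted p = 0.262 with an estimated correlation. Cyp3a11 differed by +0.46 (adjusted p = 0.229) and Gstp1 by -0.52 (adjusted p = 0.0671), 0 of 18 passed limma over all probe sets, and adjusted over the list alone 6 rose and 1 fell. Outside the lists, Ttc39c (-0.66, adjusted p = 0.052), the apolipoprotein Apom (-0.42, adjusted p = 0.063) and Sybu (+0.28, adjusted p = 0.0609) were among the genes with the smallest p and did not pass. Stellate cell and fibroblast markers, 4 of which another list holds, had a median of +0.15 and 0.09, 0.36 and 0.08 within batches, with 6 of 8 switched livers above the lifelong mean score and 0 of 15 passing limma over all probe sets or adjusted over the list alone. The camera adjusted p of these markers was 0.00116, adjusted p = 0.365 with an estimated correlation, and the call was lost in batch G150 alone. Macrophage (+0.09, camera adjusted p = 0.331), B cell (-0.04, with a mean of 0.05 of the opposite sign, camera adjusted p = 0.865) and hepatocyte markers (-0.01, camera adjusted p = 0.743) did not pass as lists. Acute phase genes were called higher in camera, with mean scores of 0.09 in lifelong and 0.35 in switched livers (6 of 8 above the lifelong mean). Cell cycle, fetal and liver tumour, autophagy and metallothionein lists were also called higher, and cholesterol synthesis and ribosomal protein lists lower. Of the 14 lists called, only the 2 sex-biased lists passed with an estimated correlation.

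The count of 7 in switched against lifelong livers became 36, 3, 2, 1, 3, 2 and 1 without lifelong replicates 1 to 7 in turn, and 2, 27, 12, 3, 2, 13 and 3 without switched replicates 1, 3, 4, 5, 6, 7 and 8 in turn. Cyp2b13 passed in each of the 15 fits that left out 1 liver, Hao2 was lost without lifelong replicate 4 and without lifelong replicate 7, and Cbr1, Susd4 and Cyp2d9 were lost in 10, 9 and 9 of these fits, while limma on the 2 groups alone gave 0 probe sets, with 2492 at an unadjusted p under 0.05. In batch G150 alone, with array weights and with a replicate block 2 probe sets passed, those of Cyp2b13 and Hao2, and without the pair of arrays with an added suffix that of Cyp2b13 passed alone. In G151 with G152, 1 probe set passed and these 5 genes were lost.

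**Figure D4:**
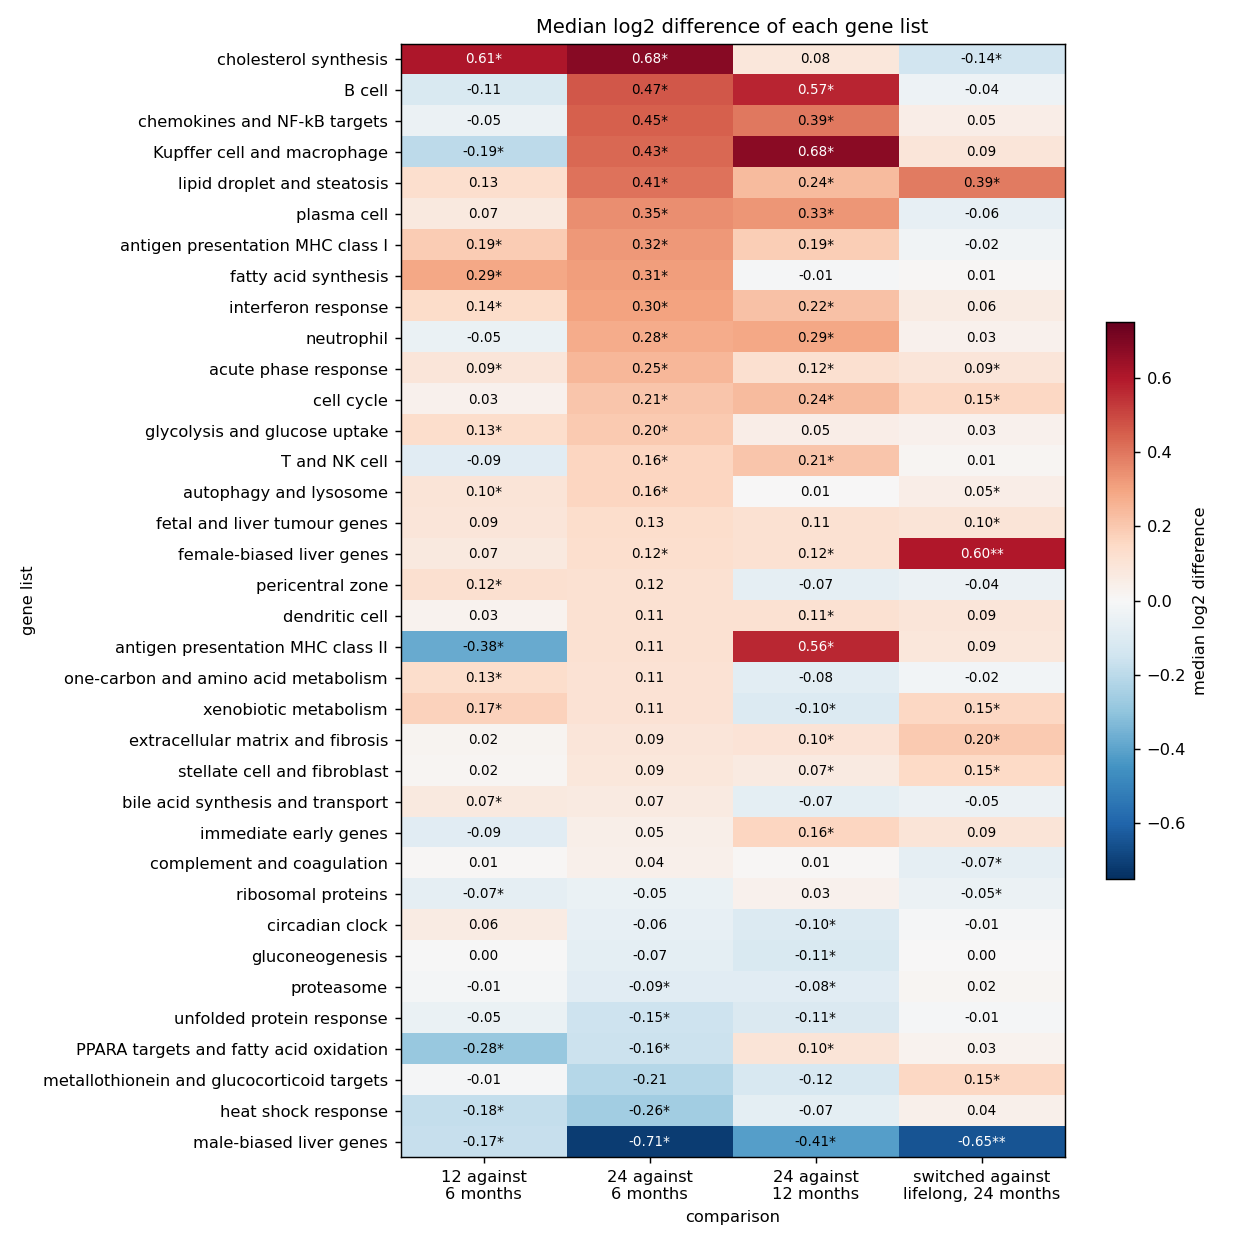
Median log2 difference of each gene list called in at least 1 comparison (36 of 48 lists) in the 4 comparisons, red for higher and blue for lower in the group named first. An asterisk marks a camera adjusted p under 0.05 and a pair of asterisks marks lists that also passed with an estimated correlation, female-biased (+0.60) and male-biased (-0.65) genes in switched livers.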

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

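The patterns weighed here were picked from the tables of single genes, and the tests of their explanations were set before the values of those tests were seen, except the exact permutation tests of list scores in switched against lifelong livers and of the B cell score alone, the contrast with cholangiocyte markers and the tests with an estimated correlation, which were chosen afterwards. A liver counts as apart when its gap to the nearest liver of its group, divided by the range of the group, exceeds Dixon's critical value for the size of the group. Among 353 pairs of a gene or list with a group, a liver was apart in 19, and chance gives about 18; some livers were apart in several of these pairs.

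Lifelong replicate 1 at 24 months was the highest of its group in Cyp2b13 (6.25 log2 units, ratio 0.767), Cyp3a11 (ratio 0.616) and the female-biased score (ratio 0.577), and the lowest in Slco1a1 (ratio 0.788). Replicate 6 at 6 months was the highest in Hyou1 (ratio 0.637), Igkc (ratio 0.771) and the circadian clock score (ratio 0.749). Switched replicate 3 was the highest in Cyp2d9 (ratio 0.572) and the male-biased score (ratio 0.591), and switched replicate 1 in the neutrophil score (ratio 0.624). Replicate 1 at 12 months was the lowest in Slc2a2 (ratio 0.797) and the male-biased score (ratio 0.597). Other livers at 12 months were replicate 7 in the NF-kB score (highest, ratio 0.69) and replicate 4 in the circadian clock score (highest, ratio 0.652). At 24 months, lifelong replicate 4 was the lowest in Cyp2b9 (ratio 0.596), replicate 6 the highest in Pfkfb3 (ratio 0.626) and replicate 7 the highest in the unfolded protein response score (ratio 0.616). At 6 months, replicate 5 was the highest in Slc22a26 (ratio 0.627) and replicate 1 in the xenobiotic metabolism score (ratio 0.6253).

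Female-biased genes were higher and male-biased genes lower in switched than in lifelong livers at 24 months. Hybridisation shared within gene families is argued against, since the 8 female-biased genes outside the Cyp, Mup, Sult and Ugt families kept a median of 0.49 (camera p = 7.74e-09, p = 0.000721 with an estimated correlation, two-sided exact permutation p = 0.00109 for their score). A single extreme animal is argued against by the largest p of the female-biased list over the 15 fits that each left out 1 liver (camera p = 4.16e-16, two-sided exact permutation p = 0.00117), and array batch by the smallest within-batch median of 0.36. A female animal is argued against, since no liver lay more than 0.745 log2 units from the median of all livers in Xist or 3 Y-linked genes. A wrong group label of lifelong replicate 1 stays open, since its Cyp2b13 level (6.25), female-biased score (0.62) and male-biased score (-0.80) lie within the ranges of switched livers and these sex-linked genes cannot show an exchange between groups of males, though that liver lessens the difference rather than makes it (7 probe sets passed with and 36 without it); a difference in diet history or week of the diet cycle stays open too, so that a lasting effect of the early diet on sex-biased genes may be put forward only as a hypothesis.

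B cell and immunoglobulin transcripts were higher at 24 than at 6 months, as list shifts in camera in which 5 of 12 B cell and 3 of 11 plasma cell genes passed. With an estimated correlation these 2 lists did not pass in camera (adjusted p = 0.262 and adjusted p = 0.216). A lower share of hepatocytes would raise markers of every other cell type alike, but the B cell score rose by 0.45 while the endothelial score changed by -0.06 (two-sided exact permutation p = 0.00233 over 1716 splits). The same contrast gave an exact permutation p of 0.0117 against cholangiocyte markers and of 0.0548, which did not pass, against stellate cell markers, whose score changed by 0.10. A single extreme animal is argued against by the largest p of the B cell list over the 13 fits that each left out 1 liver (camera p = 7.41e-06, two-sided exact permutation p = 0.0455), and array batch by the smallest within-batch median of 0.36. The rise was not particular to B cells: the macrophage score averaged -0.26 at 6 and 0.23 at 24 months, and the neutrophil score -0.18 and 0.14. Age and time on the diet cannot be separated in these groups. A larger number of B cells in old livers, alone or together with other immune cells, stays a hypothesis.

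In other splits of the same livers, the count of probe sets could be set against chance. Between 12 and 6 months, 1 of 100 splits, the real one, gave as many as 210, and the highest of the others gave 2. Between 24 and 6 months, 1 of 100 gave as many as 1681, with 81 as the highest other, and between 24 and 12 months 1 of 100 gave as many as 9, with 1 as the highest other. Between switched and lifelong livers, 4 of 100 gave as many as 7, and the highest other gave 41, several times the real count; such a split may come from a structure of these samples, which was not tested. Chance is excluded at 5 in 100 splits for the counts between ages in the fit of all 4 groups, for which these splits were drawn. The count between 24 and 12 months rests on that fit: it was 1 in a fit of the 2 groups alone, 1 without 24-month replicate 5 and 0 in limma with a replicate block (3771 at an unadjusted p under 0.05), and other splits were not drawn for these. For switched against lifelong livers the share of 4 in 100 lies 1 split under that bar among 100 drawn of 6435, and limma on the 2 groups alone gave 0 probe sets (2492 at an unadjusted p under 0.05), so that chance is not firmly excluded for the count of 7. For lists, adjusted here within 1 comparison, 1 of 100 splits between 12 and 6 months, the real one, gave as many as 17. The highest other split gave 16, and the median of the others was 6. With p adjusted over all comparisons, the list count fell to 13 without 6-month replicate 6 and to 0 with an estimated correlation. Other splits were not drawn for these settings, so that chance is not firmly excluded for this count of lists. Chance is not excluded for the other comparisons either. Between 24 and 6 months 10 of 100 splits gave as many as 22 (highest other 28, median 13). Between 24 and 12 months 5 of 100 gave as many as 25 (highest other 28, median 11). Between switched and lifelong livers 36 of 100 gave as many as 14 (highest other 29, median 12).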

How the results depend on the processing

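The 1-gene fit and the fit without the suffixed arrays were chosen after seeing the data. Counts of probe sets are given for 12 with 6 months, 24 with 6 months, 24 with 12 months and switched with lifelong, in this order, beside 210, 1681, 9 and 7. No batch term gave 108 for 12 with 6 and 3 for 24 with 12 months. Batch G150 alone gave 0, 194, 0 and 2 in limma, with 2497 and 3415 at an unadjusted p under 0.05 behind the 0s. Batches G151 and G152 alone gave 0, 3, 0 and 1, with 2957 and 2037 behind the 0s; in these settings fewer arrays were fitted. Fits of only the groups compared gave 22, 736, 1 and 0, with 2492 behind the 0. Leaving out the lowest 30 percent of probe sets gave 33 for 24 with 12 months. Array weights gave 518 for 12 with 6 months, 23 for 24 with 12 months and 2 for switched livers. The replicate block with batch gave 122, 0 and 2 in the same comparisons, with 3771 behind the 0, and 85 of the 122, 1169 of 1334 and 2 of 2 were shared with the counts above. Only probe sets with 1 gene gave 332 for 12 with 6 and 31 for 24 with 12 months. Leaving out the pair of suffixed arrays gave 46, 39 and 1 for 12 with 6 months, 24 with 12 months and switched livers. The other counts of probe sets stayed within 1.5 times, the cause of the rest was not tested, and repeated quantile normalisation, centring and trend with robust moderation moved none past 1.5 times, though repeated quantile normalisation turned the majority at 24 with 6 months from lower (934 of 1681) to higher (852 of 1664).

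Leaving out 1 liver at a time gave 7 (6-month replicate 4) to 546 (6-month replicate 1), 831 (6-month replicate 3) to 2370 (24-month replicate 7), 1 (24-month replicate 5) to 124 (24-month replicate 4) and 1 (lifelong replicate 4) to 36 (lifelong replicate 1) probe sets. Lists passing ranged from 13 to 18, 20 to 25, 22 to 26 and 11 to 18. With an estimated correlation, camera passed 0, 0, 0 and 2 lists, with 7, 9, 7 and 7 at an unadjusted p under 0.05; 11 to 25 lists passed with no batch term, in G150 alone, without the lowest 30 percent, with repeated quantile normalisation, with the block and without the suffixed arrays, the other settings run for lists. Of the named genes over the settings that did not leave out 1 liver, 1060 values kept their direction and side of the threshold, 52 gained and 252 lost the call, and 0 reversed. Replicate numbers do not pair the mice. Pearson's r between livers of different groups was taken on deviations from the group means, over probe sets brighter than the median. Same-number pairs had a median r of -0.013, other pairs -0.006. Arrays limit dim genes, since signal over background was not measured. Between batches 650 probe sets differed.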

Other observations

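The test of the early age change was set before its values were seen, and its exact permutation form and the estimated correlation were chosen afterwards. Further list shifts lay between ages. Neutrophil markers had a median of +0.29 at 24 against 12 months, with 0 of 12 passing limma over all probe sets, 1 risen when adjusted over the list alone, and 0.35, 0.39 and 0.17 within batches (camera adjusted p = 3.07e-06, adjusted p = 0.262 with an estimated correlation). T and NK cell markers had a median of +0.21 and 0.13, 0.33 and 0.26 within batches, with 0 of 20 passing limma over all probe sets or adjusted over the list alone (camera adjusted p = 8.15e-06, adjusted p = 0.34 with an estimated correlation). Circadian clock genes had a median of -0.10 and -0.11, -0.18 and -0.21 within batches, 0 of 17 passing limma over all probe sets or adjusted over the list alone (camera adjusted p = 0.0104, adjusted p = 0.216 with an estimated correlation). Immediate early genes had a median of +0.16 and 0.13, 0.13 and 0.20 within batches, with 0 of 18 passing limma over all probe sets and 1 fallen when adjusted over the list alone (camera adjusted p = 0.00734, adjusted p = 0.334 with an estimated correlation). Behind the counts of 0 are 3953 probe sets at an unadjusted p under 0.05.

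Between 12 and 6 months, one-carbon and amino acid metabolism had a median of +0.13 and 0.15, 0.11 and 0.12 within batches, 0 of 19 passing limma over all probe sets and 2 risen when adjusted over the list alone (camera adjusted p = 0.000976, adjusted p = 0.435 with an estimated correlation). Ribosomal protein genes had a median of -0.07 and -0.06, -0.02 and -0.12 within batches, 0 of 22 passing limma over all probe sets and 1 fallen when adjusted over the list alone (camera adjusted p = 0.000454, adjusted p = 0.293 with an estimated correlation). Of the 48 lists, 12 passed in none of the comparisons, oxidative phosphorylation, NRF2 targets, the GH and IGF axis, p53 targets and senescence, and endothelial, cholangiocyte and hepatocyte markers among them.

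A hypothesis was that switched livers lie further along the change seen between 6 and 12 months. With each gene taken at its brightest probe set, 102 genes higher at 12 than at 6 months had a median of 0.02 in switched against lifelong livers (camera p = 0.0307, p = 0.487 with an estimated correlation, two-sided exact permutation p = 0.762 for their score), and 54 genes lower at 12 months had a median of 0.01 (camera p = 0.426, two-sided exact permutation p = 0.926 for their score). The hypothesis needs the second set to lie lower, which these values do not show, and a median near 0 over genes that go both ways leaves it open. Whether switched livers lie further along the change after 12 months was not tested.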
